A study of Homo sapiens with 9 samples.

How the data were processed

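The samples were Hs683 cells, an established human glioma cell line, infected with 1 of 3 short hairpin RNA vectors. The hairpins shQk-2 and shQk-5 are directed at QKI (Quaking), an RNA-binding protein of the STAR family, and shGFP, directed at green fluorescent protein, was the control. RNA from each hairpin was measured on 3 arrays, 9 in all, and the groups were taken from the source name in the labels. The titles of the shQk-5 arrays carry another digit than the hairpin's name, so the numbering of the hairpins rests on the source name alone. Within a hairpin the arrays are called a, b and c in the order of the labels. The letters did not pair the samples, as the closing section reports.

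The deposited values are an intensity for each of 54675 probe sets per array, on a linear scale. The submitters' processing notes name MAS5, the Affymetrix statistical algorithm, as the tool that made them. Its version and scaling target are not given in the sources used here, and no detection calls were used. The highest median signal of an array was 1.56 times the lowest, 9.5. Because this ratio exceeded 1.5, each array was scaled to the same median, as a rule fixed in advance required.

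Signals were then taken as log2(signal + 3), where the pseudocount of 3 is the 25th percentile of all deposited values rounded to a whole number. Of the probe sets, 41091 named a single gene, 1801 named several genes, 11721 named none and 62 were controls. Each of 19775 genes was represented by its brightest single-gene probe set over all 9 arrays. The upper 50% of genes by mean log2 signal, 9888 genes, were tested, and their mean signal was at least 23.3. Signal over background, not a count of molecules, therefore limits what could be measured, and the number of arrays limits the precision.

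Groups were compared with limma 3.58.1 in R 4.3.3. A linear model with 3 group means was fitted to all 9 arrays, which left 6 residual degrees of freedom, and the variances were moderated with a trend on brightness (median prior degrees of freedom 11.5). The contrasts were shQk-2 against shGFP, shQk-5 against shGFP, the average of both hairpins against shGFP, and shQk-2 against shQk-5. Adjusted p-values are Benjamini-Hochberg values over the genes tested, two-sided, and a gene was called at an adjusted p under 0.05. Fold changes are log2 differences of group means with their standard error (SE). For QKI, every probe set was also tested on its own, and an exact permutation test was run per hairpin. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

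The genes named in the text followed a rule. It took every QKI probe set, and up to 10 higher and 10 lower genes called with both hairpins in the same direction. It took the 5 higher and 5 lower called genes with the largest fold change for each hairpin against shGFP and for the hairpins against each other. Genes taken this way had arrays that did not overlap between the groups, so all 3 arrays of a hairpin lay on the same side of all 3 arrays it was compared with. It also took up to 4 members of each gene list called for the average of both hairpins, and TGFBR2, SMAD2, SMAD3, SMAD4 and MIR17HG if measured. Some genes the rule names, and a gene list, are not reported here. Other genes named as members of a list, and MT1E, SLC30A1 and the single NRF2 targets named, were chosen after their values were seen.

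In all, 27 gene lists were compared, with 498 distinct genes, of which 361 were tested. The lists reported cover TGF-beta response genes, TGF-beta pathway components, targets of the miR-17/20a family, microRNA processing, G2/M and mitosis, DNA replication, interferon-stimulated genes, NF-kB targets and cytokines, and fibrillar collagens and matrix. They also cover actin cytoskeleton and adhesion, cholesterol synthesis, hypoxia, the unfolded protein and ATF4 response, immediate early genes, ribosomal proteins, oxidative phosphorylation, splicing regulators, mRNAs reported to bind or respond to QKI, and housekeeping controls. Markers of oligodendrocytes, astrocytes, neurons, neural progenitors, fibroblasts, endothelial cells, and microglia and leukocytes completed them. The list of microglia and leukocyte markers had 0 tested members and gave no result. The fibroblast and matrix lists share 5 genes. Lists were tested against all other genes with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Each test was repeated with the correlation estimated per list, and with fry, which tests whether the genes of a list move on balance one way without comparing them with other genes. Among the 36 calls of camera, 2 held with an estimated correlation (cholesterol synthesis with shQk-2 and for the average of both hairpins) and 15 with fry. A call lost with an estimated correlation need not have been lost through correlation between members. With shQk-2 the fibroblast markers had an estimated correlation of -0.005, below the preset 0.01. Their camera adjusted p still went from 0.00122 to 0.0860. Samples, contrasts, lists, the naming rule and most alternatives were fixed before the data were examined.

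The alternatives were quantile normalization, scaling to the 75th percentile, other pseudocounts, other filters, the mean of all probe sets of a gene or every probe set on its own, moderation without a trend or with robust priors, array weights, a block for the replicate letter, fits to only the arrays compared, and leaving out each array in turn. Unscaled signals, and scaling to the mean of the middle 96% of signals, were added after the data had been seen. The gene lists were run under these scalings too, of which only quantile normalization was planned for them. The closing section gives their effects.

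The tests were checked on simulated data made from these arrays, with the comparison of shQk-2 with shGFP. Noise was drawn independently for each gene from the fitted variances, so correlation between genes was not part of this check. Over 5 runs, 43% of genes changed by a log2 of 0.5 and 88.6% of those changed by a log2 of 1 were recovered, 100% with the right sign, beside 9.4 false calls per run. Because both hairpins were compared with the same 3 shGFP arrays, 100 simulations of unchanged groups sharing a control gave a correlation to set beside the observed one. The labels do not say that the arrays of a hairpin came from separate cultures, so the p-values measure only the spread between these samples.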

Results

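Gene expression was measured in Hs683 glioma cells infected with a hairpin against QKI, shQk-2 or shQk-5, or with the control hairpin shGFP. There were 3 arrays per hairpin. The median deposited signal of an array ran from 9.5 in the lowest (shGFP c) to 1.56 times that value in the highest (shQk-2 b), and 9888 of 19775 genes were bright enough to be tested. The array shGFP b stood apart in its signal for the 18S ribosomal RNA control, 62.4, beside 123.7 to 239.5 on the other 8 arrays. Its mean rank correlation with the other arrays was the lowest, 0.884, but close to those of the rest (0.886 to 0.895). All shGFP arrays correlated less with their own group (0.884 to 0.888) than the hairpin arrays with theirs (0.892 to 0.899). With 3 arrays per group, an exact permutation test cannot give a two-sided p below 0.1 for any single gene, so the calls rest on the model across genes.

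QKI, the target of both hairpins, fell with each of them. On its brightest probe set the mean signal was 459.6 ± 23.1 (SD, n = 3) with shGFP, 312 ± 15.2 with shQk-2 and 254 ± 38.1 with shQk-5. The fitted changes were -0.55 (SE 0.11, adjusted p = 0.0159) and -0.86 (SE 0.11, adjusted p = 0.00144) on the log2 scale, or 68.1% and 55.1% of the shGFP level. All 3 arrays of each hairpin lay below all 3 shGFP arrays (exact permutation p = 0.1, two-sided, the smallest possible). QKI was further below shGFP with shQk-5 than with shQk-2, and all 3 shQk-5 arrays (210 to 282) lay below all 3 shQk-2 arrays (300 to 329). The difference of 0.31 did not pass the test over all genes (adjusted p = 0.21), which leaves its size unsettled.

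The next 4 QKI probe sets by brightness had 42.1% to 52.98% of the shGFP level with shQk-2 and 33.6% to 40.6% with shQk-5. In a fit to every probe set they were called with both hairpins, except the dimmest of them with shQk-5 (adjusted p = 0.0790). A dim probe set, with a signal of 42.1 in shGFP, had 14.77 ± 2.21 with shQk-2 (adjusted p = 0.147) and 2.95 ± 2.81 with shQk-5 (adjusted p = 0.00455), which is about the pseudocount, so no share of the shGFP level is given for it. Another, with a signal of 17.6, had 118% and 114% and was not called (adjusted p = 0.775 and 0.890), and 3 further QKI probe sets were too dim to be tested. The call of QKI with shQk-2 was lost without shQk-2 a (adjusted p = 0.0712), shQk-2 b (0.0590) or shGFP c (0.0638), and on unscaled signals (-0.27, adjusted p = 0.191), within a range of 0.00202 to 0.191 over its 23 alternatives. With the mean of all QKI probe sets the changes were -0.67 (adjusted p = 0.0971) and -1.03 (adjusted p = 0.0593), and without a variance trend both calls were lost too (adjusted p = 0.105 and 0.107), while those with shQk-5 ranged from 0.000223 to 0.107.

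**Figure D1:**
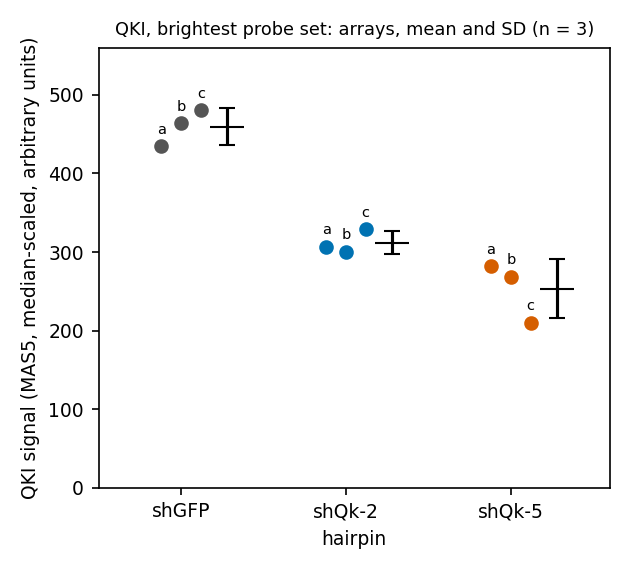
Signal of QKI (brightest probe set, arrays scaled to the same median, axis from 0) on each of the 9 arrays, by hairpin, with the group mean and SD (n = 3). The means are 459.6 with shGFP, 312 with shQk-2 and 254 with shQk-5, and no hairpin array reaches a control array.

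The comparison of shQk-2 with shGFP asks what differed in cells with this hairpin. The largest rise was in CXCL8, a chemokine that attracts neutrophils, whose mean signal was 31.6 ± 2.15 (SD, n = 3) with shGFP and 108 ± 27.4 with shQk-2 (log2 1.66, SE 0.22, adjusted p = 0.000365). PTX3, a secreted pentraxin of innate immunity, rose from 124 ± 18.6 to 297 ± 58.9 (log2 1.23, SE 0.14, adjusted p = 0.000116). GDF15, a stress-responsive cytokine of the TGF-beta superfamily, fell from 281 ± 23.4 to 112 ± 13.1 (log2 -1.30, SE 0.11, adjusted p = 1.16e-05). HGF, the ligand of the MET receptor, rose by 0.92 (adjusted p = 7.37e-05), STMN3, a stathmin that destabilizes microtubules, by 0.90 (0.000136) and PIGW, an enzyme of membrane anchor synthesis, by 0.88 (0.0258). The other genes that fell most were the sugar transporter SLC50A1 (-1.57, adjusted p = 0.00543), the collagen chaperone SERPINH1 (-1.49, 0.0173), the metalloproteinase inhibitor TIMP4 (-1.35, 0.0179) and the immediate early factor EGR1 (-1.32, 0.00303). The signal of SERPINH1 with shQk-2, 13.0, lay below 23.3, the lowest mean signal of the genes tested, so the size of its fall is uncertain. On the log2 scale SLC50A1 with shQk-2 also lay just below that lowest mean, so the size of its fall is uncertain too.

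In all, 153 genes were called with shQk-2, 38 higher and 115 lower, of which 91 differed by more than 1.5-fold and 22 by more than 2-fold. The share of lower genes was 75.2% here, 60.5% after quantile normalization, 63.8% with scaling to the 75th percentile, 64.8% with scaling to the trimmed mean and 2.72% on unscaled signals. Without scaling, the median of all genes shifted by 0.30 with shQk-2, 0.15 with shQk-5, 0.23 for their average and 0.15 between the hairpins. A list median that was positive on unscaled signals could therefore still lie below that of all genes. Groups did not overlap for 19.1% of genes, where chance gives 10% on average over groupings. Because genes are correlated, the share in a single grouping can lie well away from 10% without any change. The count was 78 without shQk-2 a, 94 without shQk-2 b, 66 without shQk-2 c and 69 without shGFP b. The call of PIGW was lost without shQk-2 a, b or c or shGFP b (adjusted p up to 0.104), that of SERPINH1 without shQk-2 a or b or shGFP b or c (up to 0.0860), and that of TIMP4 without shGFP c (0.0638). Of 4 dimmer probe sets of HGF, 2 were not higher with shQk-2 (0.01 and -0.29). The dimmer probe sets of EGR1 gave smaller falls with shQk-2, -0.41 and -0.59.

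Genes of cholesterol synthesis were lower as a group with shQk-2. Of 16 tested members 15 had lower values, with a median of -0.40 (camera adjusted p = 5.62e-10, and adjusted p = 0.0205 with an estimated correlation). With an estimated correlation the call held in only 3 of the 9 fits without 1 array, and was lost without any of the shQk-2 arrays, shQk-5 b or shGFP a or c (adjusted p up to 0.0958, without shQk-2 c). INSIG1, a sterol-regulated protein of the endoplasmic reticulum, fell by 1.10 (adjusted p = 0.000479), IDI1 by 0.56 (0.0231), SQLE by 0.55 (0.0225) and LSS by 0.48 (0.0245), and 8 members were lower when adjusted over the list alone. Genes of the hypoxia response were lower too, 17 of 19 with a median of -0.38 (camera adjusted p = 1.88e-14, but adjusted p = 0.0860 with an estimated correlation). In that list 6 fell, among them the glycolytic enzyme ALDOC (-1.22, adjusted p = 7.37e-05), LOX, which crosslinks collagen (-0.82, 0.000208), the growth factor VEGFA (-0.75, 0.000768) and NDRG1 (-0.68, 0.000558), and 12 were lower adjusted over the list alone.

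The list of fibrillar collagens and matrix had a median of -0.23 with shQk-2, which was positive on unscaled signals (camera adjusted p = 0.000128, but adjusted p = 0.163 with an estimated correlation). COL1A2, COL12A1, COL11A1, POSTN and LOX fell, led by COL1A2 (-0.84, adjusted p = 0.00272), while 16 of the 21 members did not pass the test. Adjusted over the list alone, 9 were lower and 3 higher. The fibroblast markers, 5 of which are also in the matrix list, had a median of -0.33 (camera adjusted p = 0.00122, but adjusted p = 0.0860 with an estimated correlation), and COL1A2 and THY1 (-0.63, adjusted p = 0.0233) fell. Other probe sets bright enough to be tested gave -0.08 and -0.10 for THY1, and as little as -0.15 for LOX and 0.16 for COL12A1. The 5 astrocyte markers had a median of -0.13, positive on unscaled signals (camera adjusted p = 0.000523, but adjusted p = 0.104 with an estimated correlation), and ALDOC alone fell among them. On unscaled signals camera at the preset correlation still called the matrix and astrocyte lists lower. Where 1 array was left out, the median of the matrix list ran from -0.26 to -0.10 (without shGFP b) and that of the astrocyte markers from -0.24 (without shQk-2 c) to -0.12.

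Other lists gave calls with shQk-2 that were all lost with an estimated correlation. The unfolded protein and ATF4 list had a median of -0.17, positive on unscaled signals (camera adjusted p = 0.000893, but adjusted p = 0.163 with an estimated correlation), and PHGDH, an enzyme of serine synthesis, fell in it (-0.65, adjusted p = 0.0180). Immediate early genes had a median of -0.18, positive on unscaled signals (camera adjusted p = 0.000697, but adjusted p = 0.280 with an estimated correlation), with EGR1 and JUND (-0.47, adjusted p = 0.0471) lower. Targets of the miR-17/20a family had a median of -0.10, positive on unscaled signals (camera adjusted p = 0.00863, but adjusted p = 0.280 with an estimated correlation), and CDKN1A, an inhibitor of the cell cycle, fell in it (-1.11, adjusted p = 0.000768), as did VEGFA. TGF-beta response genes had a median of -0.11, positive on unscaled signals (camera adjusted p = 0.0186, but adjusted p = 0.453 with an estimated correlation), and BHLHE40 (-0.48, adjusted p = 0.0378) and POSTN (-0.79, 0.0160) fell. The camera call of this list was lost without shQk-2 b (adjusted p = 0.0555), after quantile normalization (0.0820) and on unscaled signals. Mitotic genes had a median of 0.13 (camera adjusted p = 0.0103, but adjusted p = 0.669 with an estimated correlation) and replication genes 0.19 (0.0355, but adjusted p = 0.669 with an estimated correlation), with 0 members called by limma in either. The mitotic list was not called without shGFP a (adjusted p = 0.119) or shQk-2 c (0.0508), nor the replication list without shQk-2 c (0.156), shGFP a (0.134) or shGFP b (0.0851). Housekeeping controls, with 0 members called over all genes but 7 of 13 lower adjusted over the list alone, had a median of -0.26, positive on unscaled signals (camera adjusted p = 1.77e-05, but adjusted p = 0.280 with an estimated correlation). Ribosomal protein genes had a median of -0.14, positive after quantile normalization and on unscaled signals (camera adjusted p = 0.0116, but adjusted p = 0.669 with an estimated correlation), and lost the call without shGFP c (0.246), shQk-2 b (0.113) or shQk-2 c (0.0710). Several of these medians moved with single arrays: immediate early genes ran from -0.28 (without shGFP a) to -0.12 (without shQk-2 b), miR-17/20a targets from -0.19 (without shQk-2 c) to -0.05 (without shQk-2 a), TGF-beta response genes up to -0.06 (without shGFP b), and ribosomal genes up to -0.05 (without shGFP c). Mitotic genes ran from 0.05 (without shQk-2 c) to 0.21 (without shGFP c), and replication genes down to 0.10 (without shGFP b). On unscaled signals camera at the preset correlation still called the unfolded protein, immediate early, miR-17/20a and housekeeping lists lower. It did not call the TGF-beta response and ribosomal lists there, and the direction of the ribosomal test turned.

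The comparison of shQk-5 with shGFP asks the same of the other hairpin. HMOX1, the heme-degrading enzyme heme oxygenase, rose from a mean signal of 108 ± 17.0 (SD, n = 3) to 300.3 ± 7.60 (log2 1.47, SE 0.13, adjusted p = 1.72e-05). ENPP2, which makes lysophosphatidic acid, rose by 0.91 (adjusted p = 0.0222), the cytokine receptor LIFR by 0.87 (0.0128), SCML1 by 0.76 (0.0222) and the steroid reductase SRD5A1 by 0.72 (0.0450). IGFBP5, which binds insulin-like growth factors, fell from 2974 ± 161 to 1572 ± 146 (log2 -0.92, SE 0.10, adjusted p = 0.000103). L3HYPDH, a dehydratase of hydroxyproline, fell by 1.11 (adjusted p = 0.00758), the collagen chain COL1A2 by 0.90 (0.00655) and the neuropeptide precursor NMB by 0.89 (0.0265).

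With shQk-5, 27 genes were called, 9 higher and 18 lower, of which 22 differed by more than 1.5-fold and 2 by more than 2-fold. The share of lower genes was 66.7%, but 54.5% with scaling to the trimmed mean, 15.4% on unscaled signals, 45.8% without shQk-5 c and 50% without shGFP b. Groups did not overlap for 14.6% of genes, where chance gives 10% on average, with the same limit. The count was 5 without shQk-5 b and 10 without shGFP c, and 1 with moderation without a trend. The calls of HMOX1, IGFBP5 and COL1A2 held in all 9 fits without 1 array. L3HYPDH lost its call without shQk-5 b or shGFP c (adjusted p up to 0.0604), LIFR without shQk-5 b or c or shGFP c (up to 0.0604), ENPP2 without any of the shQk-5 arrays or shGFP a or b (up to 0.1004), and NMB without shQk-5 b or c or any shGFP array (up to 0.103). SCML1 lost it without shQk-5 a or b or shGFP a or c (up to 0.135), and SRD5A1 in 8 of the 9 fits, all but the fit without shGFP b (up to 0.176).

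Few list members passed the test with shQk-5. Cholesterol synthesis genes had a median of -0.23, with 13 of 16 lower (camera adjusted p = 3.88e-05, but adjusted p = 0.101 with an estimated correlation). None of them was called over all genes, and IDI1 (-0.57), SREBF2 (-0.50) and LSS (-0.40) were lower adjusted over the list alone. The matrix list had a median of -0.14, positive on unscaled signals (camera adjusted p = 0.00414, but adjusted p = 0.369 with an estimated correlation), and COL1A2 and COL11A1 (-0.60, adjusted p = 0.0265) fell. Camera at the preset correlation still called the matrix list lower on unscaled signals. The astrocyte markers had a median of -0.27 (camera adjusted p = 0.00195, but adjusted p = 0.164 with an estimated correlation). NF-kB targets and cytokines had a median of 0.17 (camera adjusted p = 0.00648, but adjusted p = 0.164 with an estimated correlation), with 0 called over all genes and 4, CCL2, ICAM1, IL6 and MMP1, higher adjusted over the list alone. The hypoxia list had a median of -0.15 (camera adjusted p = 0.00648, but adjusted p = 0.717 with an estimated correlation), and lost its call without shGFP b (0.173) or shQk-5 a (0.0523) and on unscaled signals (0.0933). The fibroblast markers had a median of -0.15 (camera adjusted p = 0.0142, but adjusted p = 0.164 with an estimated correlation), and lost theirs without shGFP a (0.0587) or shQk-5 a (0.0516). Housekeeping controls had a median of -0.11, positive on unscaled signals (camera adjusted p = 0.0326, but adjusted p = 0.957 with an estimated correlation). They were not called on unscaled signals (0.464), after quantile normalization (0.426), or without shGFP c (0.191), shQk-5 b (0.179), shGFP a (0.0611) or shQk-2 c (0.0536). Leaving out 1 array moved the median of the NF-kB list from 0.04 (without shQk-5 a) to 0.36 (without shQk-5 c), those of the matrix and hypoxia lists to -0.08 and -0.10 (both without shGFP b), and that of the housekeeping controls from -0.17 (without shGFP a) to -0.07 (without shGFP c).

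Across both hairpins, 10 genes were called in the same direction, where independent lists would share 0.244. Both comparisons use the same shGFP arrays, so the lists are not independent and that figure is no baseline for the overlap. Simulations of unchanged groups with shared controls called a median of 0 genes in the place of shQk-2 against shGFP (mean 8.39, highest 751), so that they shared 0 says little about this overlap, and a high count can arise there without any change. The genes that rose with both were STMN3 (0.90 with shQk-2 and 0.71 with shQk-5), CACNA2D1, a calcium channel subunit (0.68 and 0.68), SRD5A1 (0.68 and 0.72) and SCML1 (0.57 and 0.76). Those that fell with both were IGFBP5 (-0.94 and -0.92), COL1A2 (-0.84 and -0.90), the membrane protein TMEM158 (-0.58 and -0.83), QKI, the coatomer subunit COPZ2 (-0.54 and -0.68) and the collagen chain COL11A1 (-0.51 and -0.60). Of these, IGFBP5 and COL1A2 were called with each hairpin in all 9 fits without 1 array. With the mean of all probe sets, however, COL1A2 lost its call with shQk-2 (adjusted p = 0.192) and shQk-5 (0.220), and IGFBP5 with shQk-5 (0.0928). Without a variance trend, the calls of IGFBP5 and COL1A2 with shQk-5 were lost too. With shQk-5, the call of STMN3 was lost without shQk-5 b (adjusted p = 0.0520), those of CACNA2D1 (up to 0.157, without shQk-5 a) and COL11A1 (up to 0.133, without shQk-5 b) in 6 fits each, and that of COPZ2 in 5 (up to 0.108, without shGFP c). With shQk-2, the call of SCML1 was lost in 8 fits, all but that without shGFP b (up to 0.129, without shQk-2 b), and that of SRD5A1 in 5 (up to 0.113, without shQk-2 a). Also with shQk-2, those of TMEM158 (up to 0.0836), COPZ2 (up to 0.137) and COL11A1 (up to 0.132) were lost without shGFP b, among 3, 5 and 5 fits, and that of CACNA2D1 without shQk-2 c (0.0721). Another probe set of SCML1 gave -0.10 and 0.37, and another of COPZ2 gave 0.39 and 0.15. The 1 gene called in opposite directions was the metallothionein MT1E, which fell with shQk-2 (-0.70, SE 0.10, adjusted p = 0.000768) and rose with shQk-5 (0.63, SE 0.10, adjusted p = 0.00758).

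Fold changes of the hairpins correlated at 0.458 across genes, which are not independent replicates, and the simulations with shared controls gave 0.455 on average (range -0.665 to 0.925). The number of shared genes was 3 without shQk-2 a, 4 without shQk-2 b, 5 without shQk-2 c, 5 without shQk-5 a, 4 without shQk-5 b and 4 without shGFP c. The share of lower genes was 60% among them and 10% on unscaled signals, and ran from 37.5% (without shGFP b) to 100% (without shQk-5 b) where 1 array was left out, so no direction prevailed in all fits.

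For the average of both hairpins, the comparison of knockdown with control, 53 genes were called, 17 higher and 36 lower. Cholesterol synthesis genes were lower as a group, 15 of 16 with a median of -0.28 (camera adjusted p = 3.97e-10, and adjusted p = 0.0197 with an estimated correlation), and INSIG1 (-0.66, adjusted p = 0.0231), IDI1 (-0.56, 0.0156) and LSS (-0.44, 0.0378) fell. With an estimated correlation the call of the list held in only 4 of the 9 fits without 1 array, and was lost without shQk-2 a or c, shQk-5 b or shGFP a or c (adjusted p up to 0.0754, without shQk-2 c). Adjusted over the list alone, 10 members were lower. For IDI1, 2 of 3 dimmer probe sets were higher with shQk-2 (0.25 and 0.74). The hypoxia list had a median of -0.28 (camera adjusted p = 1.58e-10, but adjusted p = 0.0990 with an estimated correlation), and ALDOC (-0.85, adjusted p = 0.00163), NDRG1 (-0.49, 0.00843) and LOX (-0.43, 0.0331) fell. The matrix list had a median of -0.18, positive on unscaled signals (camera adjusted p = 3.91e-05, but adjusted p = 0.146 with an estimated correlation), and COL1A2 (-0.87, adjusted p = 0.00163), COL12A1 (-0.68, 0.0148), COL11A1 (-0.56, 0.0129) and LOX fell. In the list of NF-kB targets, which was not called (camera adjusted p = 0.0593), CXCL8 rose by 0.92 (0.0335) and the collagenase MMP1 by 0.58 (0.0275). The cell cycle inhibitor CDKN1A (-0.76, adjusted p = 0.0129) and GDF15 (-0.56, 0.0113) had lower averages. With shQk-5 alone, GDF15 had 0.18 (adjusted p = 0.605), CXCL8 0.18 (0.819), LOX -0.05 (0.911), INSIG1 -0.22 (0.634) and CDKN1A -0.41 (0.355), so on these probe sets their averages rest mainly on shQk-2.

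The fibroblast markers had a median of -0.21 for the average (camera adjusted p = 0.000911, but adjusted p = 0.0780 with an estimated correlation), with COL1A2 and THY1 (-0.54, adjusted p = 0.0485) lower. The astrocyte markers had a median of -0.26 (camera adjusted p = 5.75e-05, but adjusted p = 0.0780 with an estimated correlation). Housekeeping controls, at -0.19, and immediate early genes, at -0.06, were positive on unscaled signals (camera adjusted p = 7.60e-05 and 0.0439, but adjusted p = 0.454 and 0.577 with an estimated correlation), and 3 of the 13 housekeeping controls were lower adjusted over the list alone. Ribosomal protein genes were at -0.10, positive after quantile normalization and on unscaled signals (camera adjusted p = 0.0292, but adjusted p = 0.724 with an estimated correlation). On unscaled signals camera called none of the housekeeping, immediate early and ribosomal lists for the average, but still called the matrix list lower.

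The share of lower genes for the average was 67.9%, but 50.6% after quantile normalization, 55.04% with scaling to the trimmed mean and 1.56% on unscaled signals. Leaving out 1 array also turned it, to 46.9% without shQk-5 c (34 higher and 30 lower) and 47.4% without shGFP b (10 higher and 9 lower). The count was 33 without shQk-2 c, 32 without shQk-5 a, 31 without shQk-5 b, 19 without shGFP b and 35 without shGFP c, and shGFP b is the array that stood apart. Without shGFP b, the average calls of INSIG1 (adjusted p = 0.160), IDI1 (0.105), LSS (0.205), NDRG1 (0.0542), COL12A1 (0.0919), COL11A1 (0.106), LOX (0.214), THY1 (0.248) and MMP1 (0.162) were lost, while ALDOC and COL1A2 kept theirs in all 9 fits. Without shGFP c, those of CXCL8 (0.101), CDKN1A (0.0591) and GDF15 (0.0575) were lost. Over all 9 fits, LOX lost its call in 8, CXCL8, MMP1, LSS and THY1 in 7, INSIG1 and CDKN1A in 3 and IDI1 in 2. The immediate early list lost its call without shGFP b (0.309), shQk-2 a (0.0510), shQk-2 b (0.0846), shQk-5 a (0.0780) or shQk-5 c (0.0666), and the ribosomal list without shGFP c (0.503), shQk-2 b (0.0916) or shQk-2 c (0.0717). The median of the immediate early list ran from -0.11 (without shGFP a) to 0.0011 (without shGFP b), that of the ribosomal list from -0.15 (without shGFP a) to -0.02 (without shGFP c), and that of the matrix list up to -0.12 (without shGFP b).

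**Figure D2:**
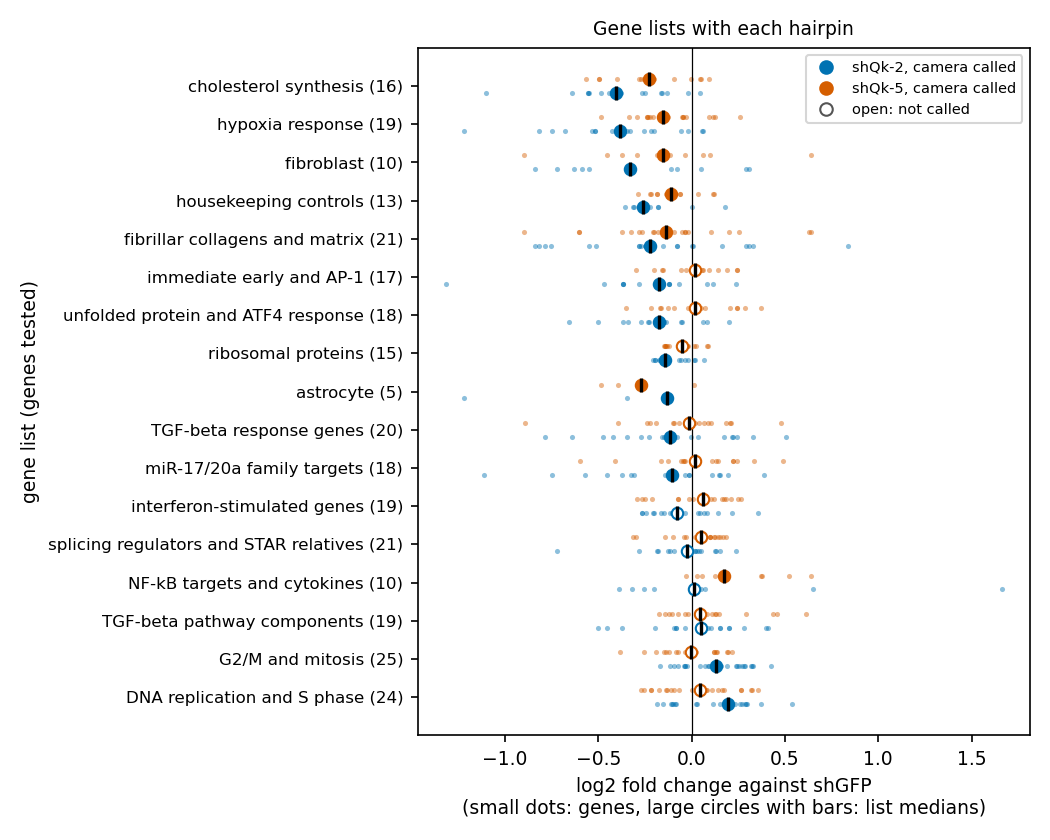
Log2 fold change against shGFP of the tested members of 17 gene lists (small dots) with each list's median (large circles, filled where camera with a preset correlation called the list). The cholesterol synthesis list has a median of -0.40 with shQk-2 and -0.23 with shQk-5, and medians of the matrix and housekeeping lists were positive on unscaled signals. With shQk-2, camera still called the matrix and housekeeping lists lower on unscaled signals.

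The hairpins were also compared with each other, to test directly where their changes differ. SERPINH1 had a mean signal of 13.0 ± 4.09 (SD, n = 3) with shQk-2, below the lowest mean of the genes tested, and 51.0 ± 12.4 with shQk-5 (log2 -1.75, SE 0.30, adjusted p = 0.00399), so it was lower with shQk-2 by an uncertain amount. Also lower with shQk-2 were TNFRSF11B, the decoy receptor osteoprotegerin (-1.63, adjusted p = 6.43e-05), TIMP4 (-1.60, 0.00399), the dehydrogenase DHRS2 (-1.53, 0.000209), HNMT, which inactivates histamine (-1.48, 6.43e-05), GDF15 (-1.48, 5.49e-07) and HMOX1 (-1.32, 2.25e-05). Higher with shQk-2 were CXCL8 (1.49, adjusted p = 0.00122), the actin-binding protein TAGLN (1.40, 0.000928), the channel protein PANX2 (1.23, 0.00340) and the lectin SIGLEC15 (1.19, 0.00952). The signal of SIGLEC15 with shQk-5, 21.5 ± 4.26, also lay below that lowest mean, so the size of its difference is uncertain too. Another probe set of TAGLN (0.18) and dimmer ones of PANX2 (-0.88) and HNMT (0.13) did not show these differences. Nor did a probe set of CXCL8 too dim to be tested, which had 1.62 with shQk-2 and 1.96 with shQk-5 against shGFP. With the mean of all probe sets, which takes in those too dim to be tested, the calls of HNMT (-0.57, adjusted p = 0.371), CXCL8 (0.58, 0.452) and PANX2 (0.63, 0.194) were lost.

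Between the hairpins 197 genes were called, 75 higher and 122 lower with shQk-2, of which 109 differed by more than 1.5-fold and 29 by more than 2-fold. The lower share was 61.9%, but 45.6% with scaling to the 75th percentile and 29.0% on unscaled signals. Of the 197 genes, 70 were also called with shQk-2 against shGFP and 9 with shQk-5. Groups did not overlap for 19.0% of genes, where chance gives 10% on average, again with the limit that genes are correlated. The count was 107 without shQk-2 a, 124 without shQk-2 b, 90 without shQk-2 c, 92 without shQk-5 a and 84 without shQk-5 b. The call of SIGLEC15 was lost without shQk-2 c (adjusted p = 0.0580).

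**Figure D3:**
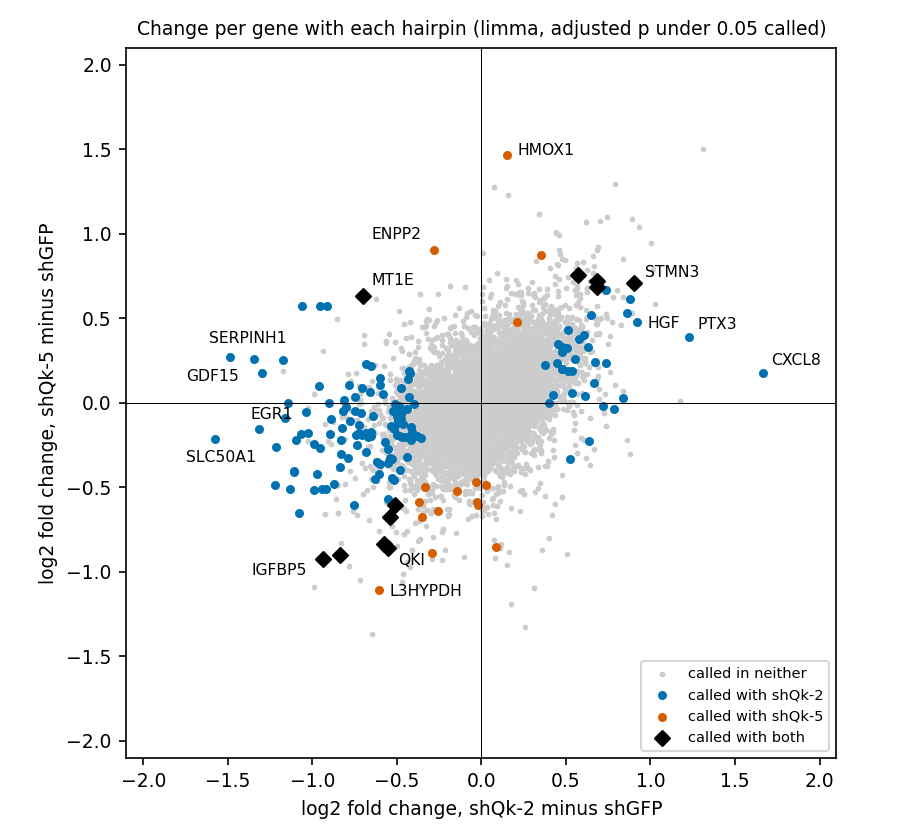
Log2 fold change of each tested gene against shGFP with shQk-2 (horizontal) and shQk-5 (vertical), with genes called with shQk-2 in blue, with shQk-5 in orange and with both as black diamonds, which include MT1E. IGFBP5 lies at -0.94 and -0.92, CXCL8 at 1.66 and 0.18, and HMOX1 at 0.15 and 1.47.

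Work on QKI in glioma has linked it to the TGF-beta receptor TGFBR2 and to the microRNA miR-20a, so these genes were named in advance. TGFBR2 had a change of -0.37 with shQk-2 (SE 0.12, adjusted p = 0.173) and 0.13 with shQk-5 (adjusted p = 0.763), and the hairpins differed by -0.50 (adjusted p = 0.0446). Over the alternatives its change ran from -0.66 to -0.09 with shQk-2 and from -0.26 to 0.27 with shQk-5. Another probe set of TGFBR2, too dim to be tested, gave -0.94 and -0.65. SMAD2, which carries the receptor's signal, fell by 0.50 with shQk-2 (SE 0.11, adjusted p = 0.0307) and had -0.02 with shQk-5 (adjusted p = 0.976), a difference of -0.48 (adjusted p = 0.0339). SMAD3 had 0.05 and 0.03, and SMAD4 had -0.45 (adjusted p = 0.198) and -0.04. MIR17HG, the host transcript of miR-20a, had a mean signal of 1.91 and was too dim to be tested. The pathway components as a list were not called (camera adjusted p = 0.880 with shQk-2 and 0.463 with shQk-5). The difference in TGFBR2 was lost in 7 of the 9 fits without 1 array (adjusted p up to 0.197, without shQk-5 b), the fall of SMAD2 in 6 (up to 0.104, without shQk-2 c) and its difference in 5 (up to 0.167, without shQk-5 b).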

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

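Among the tests in this part, the brightness-matched lists, both tests of the extent of knockdown, the share of genes kept after quantile normalization, the unscaled signals and the scaling to the trimmed mean were chosen only after the result was seen, and the metallothionein group was chosen after MT1E was seen.

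The hairpins differed from each other in 197 genes, and shared 10. A shared gene had to pass the test with each hairpin, so these counts rest on unlike thresholds. The single test of the average called 53. A deeper knockdown of QKI with shQk-5 would give most of the 197 the same sign with both hairpins and larger values with shQk-5. By their fitted values, 3.55% had this pattern (7 genes, exact 95% interval 1.44% to 7.18%). The fitted values of 150 against shGFP differed in sign, though MT1E alone was called in opposite directions. However, genes chosen for a large difference between the hairpins tend to lie on opposite sides of shGFP. Over all tested genes, 67.1% had the same sign with both, beside 65.7% on average in the simulations of unchanged groups sharing a control. That share therefore says little about agreement of the hairpins. The difference in QKI did not pass the test over all genes, though the QKI signals of the hairpins did not overlap on the brightest probe set. Because of how the genes were chosen, these shares cannot decide on the extent of knockdown. Quantile normalization kept 192 of the 197 genes (97.5%) in a longer list of 325, while unscaled signals kept 108. These values argue against array scaling as the whole cause, but not against a part in it. By camera, 0 of 23 chromosomes were called, with the largest chromosome median at 0.06. That argues against whole-chromosome copy number but says nothing of shorter segments. Effects of a hairpin on transcripts other than QKI, and differences between the infected cultures, were not tested and may both contribute, since each hairpin was measured in a single group of 3 arrays.

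Of the 10 splits of the 6 arrays in each pairwise comparison, only the real 1 gave as many genes. The real counts were 197 between the hairpins, 153 with shQk-2 and 27 with shQk-5, and the highest of the others were 0, 0 and 1. With 10 splits a share under 0.05 cannot be reached. For the average of both hairpins, 2 of 100 splits of the 9 arrays gave 53 genes or more. For genes shared by both, 2 of 100 gave 10 or more, so the share was under 0.05 for both counts. In each case the other split took the 3 shQk-2 arrays as the control (122 genes for the average and 53 shared), so the shQk-2 arrays stand apart as a structure of the samples. The 100 splits were only a part of those possible, and most mixed arrays of different hairpins. Mixing adds the differences between hairpins to the spread within groups, which holds the counts down. The shares therefore show only that the 9 arrays were not interchangeable. They cannot decide whether the real counts come from comparing the hairpins with shGFP.

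The cholesterol synthesis list was lower with the hairpins, and its median differed between them by -0.14 on scaled signals, but was positive on unscaled ones (camera adjusted p = 0.0257, but adjusted p = 0.376 with an estimated correlation). Camera at the preset correlation still called this difference on unscaled signals, in the same direction relative to other genes. The list's average median lay below all 10000 lists of matched brightness (percentile 0). With shQk-2 the housekeeping controls lay at percentile 0 too, so such a rank does not single out the cholesterol list. The largest camera adjusted p of the cholesterol list among the 9 fits without 1 array was 3.99e-07, without shGFP a. The values of this list argue against brightness-dependent scaling and a single deviating array as the whole cause. With an estimated correlation, however, the list was called in 4 of these 9 fits for the average and in 3 for shQk-2, while its median stayed between -0.31 and -0.27 for the average and between -0.41 and -0.34 with shQk-2. The member difference averaged -0.16, so the list was not lower with the hairpin that left less QKI. The difference in QKI did not pass the test over all genes, though the QKI signals of the hairpins did not overlap on the brightest probe set. The difference of the list was not called with an estimated correlation, so extent of knockdown and list level cannot be told apart here. A response to QKI loss was not tested beyond this and stays open.

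MT1E differed by -1.33 between the hairpins, lower with shQk-2 and higher with shQk-5. The other tested members of its group, 5 metallothioneins and the zinc exporter SLC30A1, had a median difference of -0.19 (camera p = 0.377 with an estimated correlation), and with 6 members the test leaves open whether the whole family shifted. SLC30A1 alone among them was called, in the other direction (0.84, adjusted p = 0.00674). The 5 metallothioneins besides MT1E were all lower with shQk-2 than with shQk-5 (-0.15 to -0.33). Against shGFP they had -0.22 to -0.37 with shQk-2 and -0.11 to 0.05 with shQk-5.

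TGFBR2 differed by -0.50 and SMAD2 by -0.48 between the hairpins, both lower with shQk-2, with calls lost in 7 and 5 of the 9 fits without 1 array (adjusted p up to 0.197 and 0.167, both without shQk-5 b). Lists whose difference between the hairpins was called by camera all lost the call with an estimated correlation. The targets of the miR-17/20a family differed by a median of -0.15 (adjusted p = 0.405 with an estimated correlation). Mitotic genes differed by 0.15 (adjusted p = 0.609 with an estimated correlation), with 0 members called. Actin cytoskeleton and adhesion genes differed by 0.091 (adjusted p = 0.609 with an estimated correlation), with TAGLN and ITGA5 higher with shQk-2, and were not called without shQk-5 c (adjusted p = 0.0803). Hypoxia genes differed by -0.20 (adjusted p = 0.337 with an estimated correlation), with ALDOC, LOX, NDRG1 and VEGFA lower with shQk-2. Unfolded protein and ATF4 genes differed by -0.18 (adjusted p = 0.337 with an estimated correlation), with ATF4 and HSPA5 lower. Immediate early genes differed by -0.22 (adjusted p = 0.493 with an estimated correlation), with EGR1 lower. Housekeeping controls differed by -0.12, positive on unscaled signals (adjusted p = 0.618 with an estimated correlation). They were not called on unscaled signals (camera adjusted p = 0.370), or without shQk-2 b (0.222), shQk-2 c (0.0735), shQk-5 a (0.0907) or shQk-5 c (0.0803). Leaving out 1 array moved the difference of the miR-17/20a targets from -0.22 (without shQk-5 c) to -0.07 (without shQk-5 a), of actin genes from 0.02 (without shQk-5 c) to 0.18 (without shQk-5 a), of immediate early genes up to -0.14 and of housekeeping controls up to -0.03 (both without shQk-2 b), and of the cholesterol list up to -0.05 (without shQk-2 c). The cholesterol list's difference was not called without shQk-2 c (adjusted p = 0.146) or shQk-5 c (0.0803).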

How the results depend on the processing

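Unscaled signals and scaling to the trimmed mean were chosen only after the data had been seen. Counts are given in the order shQk-2, shQk-5, average, between hairpins and shared by both, beside 153, 27, 53, 197 and 10, and counts not listed stayed within 1.5 times of these. Quantile normalization gave 332, 58, 156, 325 and 23, and kept 153, 27, 53, 192 and 10 of the same genes. Scaling to the 75th percentile gave 271, 47, 105, 305 and 16, and to the trimmed mean 304, 55, 129, 307 and 20. Unscaled signals gave 1694 with shQk-2, 641 for the average, 131 between hairpins and 20 shared, most of them higher, as the median of all genes was shifted upward there. Without a filter on dim genes the counts were 64, 9, 25, 94 and 4, with more genes tested, and the upper 30% of genes gave 102 for the average. The mean of all probe sets gave 74, 3, 20, 96 and 1. Moderation without a trend gave 50, 1, 3, 68 and 0 (with a trend, 1000 genes had an unadjusted p under 0.05 with shQk-5). Robust priors gave 41 with shQk-5 and 80 for the average, and array weights 54 with shQk-5, 397 between hairpins and 17 shared. Apart from these constructions, the cause was not tested.

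QKI had lower values than shGFP under all 23 alternatives for each hairpin. With shQk-2 its call was lost with the mean of all probe sets (-0.67), without a trend (-0.55) and on unscaled signals (-0.27), and with shQk-5 with the mean of all probe sets (-1.03) and without a trend (-0.86). Leaving out 1 array gave -0.59 to -0.52 with shQk-2 and -0.94 to -0.73 with shQk-5. The shQk-2 call was lost without shQk-2 a (-0.54), shQk-2 b (-0.53) and shGFP c (-0.52). Where 1 array was left out, the counts ran from 66 to 162 with shQk-2, 5 to 39 with shQk-5, 19 to 64 for the average, 84 to 228 between hairpins and 3 to 14 shared. With shQk-2 it was 78, 94 and 66 without shQk-2 a, b and c, and 69 without shGFP b. With shQk-5 it was 5 without shQk-5 b and 10 without shGFP c. For the average it was 33 without shQk-2 c, 32 and 31 without shQk-5 a and b, and 19 and 35 without shGFP b and c. Between hairpins it was 107, 124 and 90 without shQk-2 a, b and c, and 92 and 84 without shQk-5 a and b. Shared by both, it was 3, 4 and 5 without shQk-2 a, b and c, 5 and 4 without shQk-5 a and b, and 4 without shGFP c.

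Of 59 called results of named genes, 23 were kept in all 9 fits without 1 array and 10 under every alternative run. Over all their alternatives, 1025 of 1325 kept the call, 300 lost it and 0 reversed. Of the 36 list calls, 31 held after quantile normalization, 3 lost the call (TGF-beta response with shQk-2, housekeeping with shQk-5 and immediate early for the average), and the ribosomal list lost its call there with shQk-2 (adjusted p = 0.853) and for the average (0.868), where the direction of the test turned too. Genes with a mean signal under 23.3 were not tested, and a change of 0.5 was recovered for 43% of genes in the simulated data.

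The replicate letters did not pair the arrays: correlations of arrays of the same letter ran from -0.06 to 0.05, those of different letters from -0.05 to 0.07, and 2 of 9 arrays were closest to their own letter. With the replicate letter as a block, 6 genes were shared by both hairpins.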

Other observations

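Among the values in this part, those on unscaled signals, those of the lists under the scalings to the 75th percentile and the trimmed mean, and the single NRF2 targets named were chosen after the result was seen. The list of NRF2 targets was chosen after HMOX1 was seen to rise.

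Some lists were called by camera in no comparison on signals scaled to the same median. For the average of both hairpins their medians were 0.05 for TGF-beta pathway components, -0.06 for microRNA processing, 0.04 for splicing regulators and STAR relatives, 0.06 for mRNAs reported to bind or respond to QKI, 0.02 for oxidative phosphorylation and 0.0017 for interferon-stimulated genes. Those of microRNA processing were positive on unscaled signals, and those of interferon-stimulated genes negative after quantile normalization, scaling to the 75th percentile and scaling to the trimmed mean. On unscaled signals, oxidative phosphorylation was called with shQk-2 (camera adjusted p = 0.0159). Among cell type markers, the 5 tested genes of the oligodendrocyte lineage had a median of -0.07 and the 5 of neural progenitors -0.09, both positive on unscaled signals, the 4 of neurons -0.26 and the 2 of endothelial cells 0.05. Where 1 array was left out, the sign turned for neural progenitors (from -0.33 without shGFP a to 0.07 without shGFP b), endothelial cells (-0.05 without shQk-5 a), mRNAs reported to bind or respond to QKI (-0.03 without shQk-2 c), oxidative phosphorylation (-0.03 without shGFP b), splicing regulators and STAR relatives (-0.0047 without shGFP a) and interferon-stimulated genes (-0.05 without shQk-5 a). CNP, an enzyme of myelinating cells, had 0.07 with shQk-2 and -0.35 with shQk-5, and was higher with shQk-2 than with shQk-5 (0.42, adjusted p = 0.0431).

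HMOX1 is a target of the oxidative stress factor NRF2, so the other NRF2 targets were compared between shQk-5 and shGFP. The 16 tested had a median of -0.04 (camera p = 0.994 with an estimated correlation), and 0 of them were called. GCLM had 0.42 (adjusted p = 0.0758) and SLC7A11 0.37 (adjusted p = 0.121), and members went both ways. A median at or below 0 had been set beforehand as the bound against NRF2, and the median met it, but not by more than the spread of the members, a condition that was added after the values were seen. With that condition the median decides nothing about NRF2. With shQk-2, the NRF2 targets AKR1B10 (-0.66, adjusted p = 0.00448) and AKR1C1 (-0.44, adjusted p = 0.0245) fell. Between the hairpins, AKR1B10, AKR1C1 and GCLM were lower with shQk-2, while the list was not called with an estimated correlation (p = 0.136).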
